A study of Mus musculus with 4 samples.

How the data were processed

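Gamma-delta intraepithelial lymphocytes of the small intestine were profiled in 2 groups of mice, conventional and germ-free, with 2 arrays per group. Per the labels' protocols, intraepithelial cells were isolated, labelled with an antibody to the T cell receptor delta chain, and sorted. RNA was purified with a kit for small cell numbers, pooled from 5 to 8 mice per array, amplified, and labelled with biotin for Affymetrix mouse arrays. Amplification can compress or distort differences between transcripts, and a sort leaves some cells or RNA of other types, so markers of those types were measured too.

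The deposited values are linear signal intensities of 45101 probe sets, 64 of them array controls. Per the submitters' processing notes they were made with MAS5; its version is not given in the sources used here. The deposited values of every array have a mean of 500 after leaving out the lowest and highest 2% of probe sets, so each array had been scaled by 1 factor. Such scaling does not remove differences that depend on signal level. Detection calls were not used here. Since these are array intensities, no depth applies; the low end is set by background, and differences of dim genes are understated.

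Probe sets were named through the platform's annotation. Of the probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 34741 of those with 1 symbol matched an Entrez ID in a RefSeq gene table of the mouse assembly GRCm38.p6, with 0 symbols changed. Probe sets with several symbols or none were not named. No probe set with 1 symbol was found for Trdc and Ddx3y among those used here. No coordinates are given, since a genome build is not given in the sources used here.

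Values were taken to log2 after adding 36.29, the median over arrays of their 25th percentiles, so fold changes are on the log2(signal + constant) scale and understate dim genes. Each gene was represented by its probe set with the highest mean over all arrays, chosen without regard to group. Genes with a mean log2 value above 7.277 (a signal of about 119), the median of all probe sets, were tested. No further normalization was applied in the main setting. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, 2 residual degrees of freedom per gene, 7.14 after moderation) with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are conventional minus germ-free.

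Gene lists for gut lymphocytes, for the epithelium and other cells that a sort could hold, and for stress, metabolism and the cell cycle were written before the data were examined, as were the design, the rule for named genes and all alternatives but 1. The 27 lists with at least 5 tested members were tested with camera and its preset correlation, adjusted over the lists, then with the correlation estimated from the data and with fry. With the estimated correlation 0 of the 9 camera calls held, and fry called 0 lists. The estimated-correlation test draws on the 2 residual degrees of freedom, so with adjustment over 27 lists it could hardly call any. Its lost calls therefore do not show by themselves that correlation between genes ended them, nor that it did not. The estimated correlation was high for some called lists (enterocyte 0.748, cholesterol 0.521, cell cycle 0.364, ribosomal 0.297, goblet 0.272). It was low for others (T cell receptor 0.063, antimicrobial 0.0174, interferon -0.019). How far correlation and how far the few degrees of freedom ended each call was not tested. For the natural killer list the estimated correlation was -0.0542, and camera's unadjusted p still rose from 0.00198 to 0.0807. Members were also counted with the p adjusted over the list alone.

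The rule named, in each direction, up to 12 genes past the threshold with both arrays of a group above both of the other, or else those that passed and then the genes of smallest p up to 6. It also named up to 4 members per list, those of smallest p, and 14 genes always, of which 12 were found. Genes named outside it are said to be chosen after their values were seen.

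The test was checked on simulated data made from the tested genes' means and moderated spreads, over 20 runs with 200 of 11018 genes changed. It recovered 75.9% of genes changed 2-fold and 99.4% of those changed 4-fold. Of its calls 8.98% were false, more than the threshold of 0.05 allows for. Runs without change gave 1.2 called genes on average, beside 4 called higher in the real data, and 0.05 called lists. A list of genes shifted by 0.5 on the log2 scale was found in 20 of 20 runs. The simulated genes varied independently of each other. The list figures therefore do not carry over to lists whose members vary together, such as the enterocyte markers (estimated correlation 0.748). Where genes vary together, false calls can also come together, so the mean of 1.2 is no yardstick for the 4 called genes.

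The alternatives were other added constants, quantile normalization, median centring, no filter or a stricter one, the mean of a gene's probe sets, every probe set on its own, other variance models, a looser threshold, an estimated correlation, the replicate number as a block, and leaving out each array. The mean of the enterocyte markers as a covariate was added after seeing the data. That fit leaves 1 residual degree of freedom. The mean was higher on both conventional arrays (10.74 and 11.49) than on both germ-free arrays (10.03 and 9.01), so the fit cannot separate it well from group. Figures were drawn with matplotlib 3.10.9.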

Results

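The measurements were array profiles of gamma-delta intraepithelial lymphocytes (IEL), T cells with a gamma-delta receptor that sit between the epithelial cells of the gut lining. The cells were sorted from the small intestine of C57BL/6J mice on a label against the receptor's delta chain. One group of mice was raised conventionally, with intestinal bacteria, and the other germ-free, without microorganisms. Each group had 2 arrays, and each array carried amplified RNA pooled from 5 to 8 mice over 8 weeks of age. The labels do not say whether the 2 pools of a group came from separate mice. Limma's p-values therefore measure the spread between these pools, which may be partly technical. Camera with its preset correlation sets a list's members against the other genes, so there genes and not pools act as the replicates. With 2 arrays against 2, the number of arrays limits the precision, and an exact permutation test of any single value cannot give a p below 0.333.

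All 4 arrays had a 2% trimmed mean signal of 500, and their median signals lay between 118 and 136. The 34945 probe sets with 1 gene symbol covered 18193 genes, and 11018 of these passed the filter on low signal and were tested. Across the tested genes, which are not independent replicates, Pearson's r was 0.972 between the conventional arrays and 0.975 between the germ-free arrays. Between groups it ran from 0.946 to 0.972. The SD of the log2 difference was 0.377 and 0.371 within the groups and 0.399 to 0.541 between them.

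The comparison of conventional with germ-free mice asked which transcripts of sorted gamma-delta IEL differed with the presence of intestinal bacteria. Reg3b, an antibacterial lectin, was 12.9-fold higher in the conventional group (probe set 1448290_at, log2 difference 3.69, SE 0.31, adjusted p = 0.0195 by limma). Its signal was 5216 ± 2527 (SD, n = 2) in conventional and 347 ± 4.47 (SD, n = 2) in germ-free arrays. Clca1, a secreted goblet cell protein, was 7.36-fold higher (1416306_at, log2 2.88, SE 0.22, limma adjusted p = 0.0195), and Fcgbp, a component of intestinal mucus, was 4.51-fold higher (1426872_at, log2 2.17, SE 0.18, limma adjusted p = 0.0195). Slc6a20a, an amino acid transporter, was 3.91-fold higher (1427221_at, log2 1.97, SE 0.19, limma adjusted p = 0.0422). Reg3g, the other antibacterial lectin named in advance, had an 11.7-fold higher value that missed the threshold (log2 3.55, SE 0.40, limma adjusted p = 0.0581). Its signal was 947 ± 368 (SD, n = 2) in conventional arrays and, near the background of the arrays, 49.6 ± 41.0 (SD, n = 2) in germ-free arrays. Muc2, the main gel-forming mucin of the intestine, and Cyp3a25, a cytochrome P450, also had higher values that missed it (5.66-fold and 5.00-fold, limma adjusted p = 0.0515 for both).

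In all, limma called 4 genes higher and 0 lower in the conventional group, with 1021 genes at an unadjusted p under 0.05, of which 695 were higher and 326 lower. With each array centred on its median, these were 573 higher and 591 lower. The markers of intestinal epithelium described next were higher on the same arrays as the 4 called genes. Limma called 0 genes when no filter was applied, when a gene's probe sets were averaged, and without an intensity trend, with 931, 683 and 746 genes higher at an unadjusted p under 0.05. It called 0 without germ-free replicate 2 (608 higher at an unadjusted p under 0.05; Reg3b and Fcgbp adjusted p = 0.0784), 1 gene, Reg3b, without conventional replicate 2, 5 higher and 1 lower without conventional replicate 1, and 111 higher without germ-free replicate 1. Clca1 missed the threshold without conventional 1, conventional 2 or germ-free 2 (limma adjusted p = 0.0524, 0.212 and 0.0573), Slc6a20a without the same arrays (0.0769, 0.356 and 0.148), and Fcgbp without conventional 2 (0.212).

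**Figure D1:**
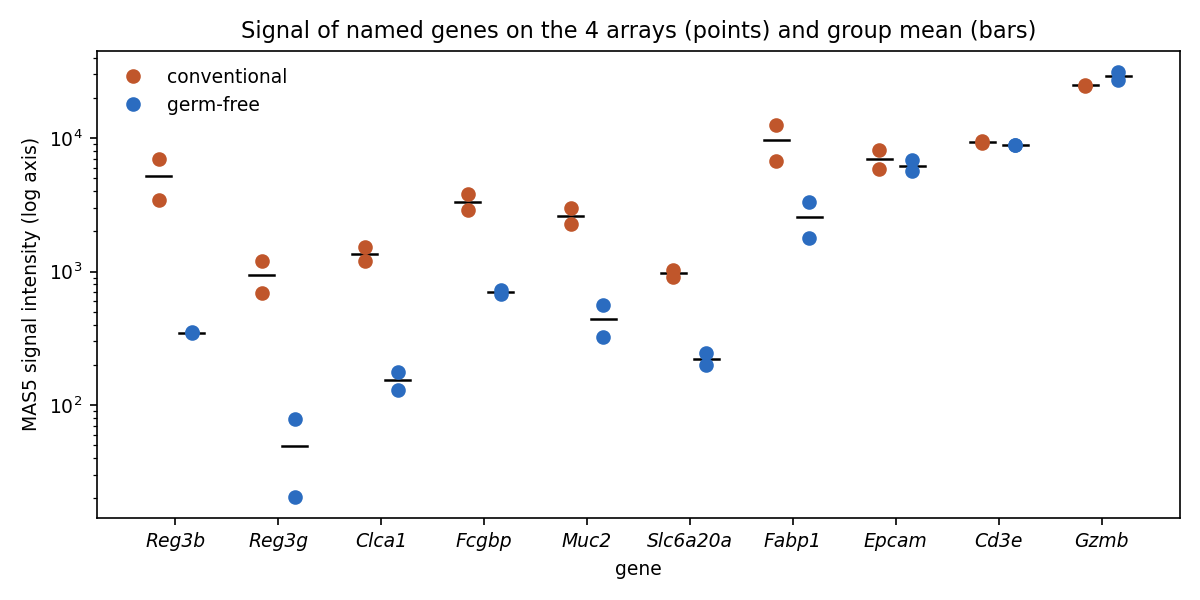
MAS5 signal intensity (log axis) of 10 named genes on the 2 conventional and 2 germ-free arrays, as points, with the group mean as a bar. The conventional points of Reg3b lie at 3429 and 7003 and the germ-free ones at 350 and 344, while those of the T cell gene Cd3e lie between 8808 and 9452.

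Transcripts of absorptive enterocytes, the main cell type of the gut epithelium, had higher values in the conventional arrays for all 29 tested members of their list, with a median log2 difference of 1.89 (3.71-fold). The members with the smallest p were Fabp6, an ileal bile acid binding protein (4.27-fold), the glucose transporters Slc5a1 (4.92-fold) and Slc2a2 (2.98-fold), and the brush border phosphatase Alpi (4.62-fold). Fabp1, a fatty acid binding protein, was 3.73-fold higher in value (log2 1.90, SE 0.35, limma adjusted p = 0.148). Over all genes tested 0 members passed, and 26 of 29 passed adjusted over the list alone. Camera placed the list above the other genes (adjusted p = 2.73e-20, but adjusted p = 0.766 with an estimated correlation). The mean log2 value of these markers also differed within the groups, at 10.74 and 11.49 on conventional 1 and 2 and at 10.03 and 9.01 on germ-free 1 and 2. Epcam, a surface protein of epithelium, had values of 7014 ± 1626 and 6215 ± 834 (SD, n = 2 each; log2 0.16, SE 0.19, limma adjusted p = 0.807), and its difference was -0.08 without conventional replicate 2.

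Goblet and Paneth cell transcripts, from the mucus-producing and the antimicrobial secretory cells of the epithelium, were higher in value for 11 of 12 tested members, with a median log2 difference of 1.94 (3.84-fold). Besides Clca1, Fcgbp and Muc2, the trefoil peptide Tff3 had a 3.40-fold higher value (limma adjusted p = 0.0895). Of these members, 2 passed over all genes tested and 9 adjusted over the list alone. The camera adjusted p was 9.69e-13, and the adjusted p was 0.663 with an estimated correlation. The list's mean log2 value was 10.17 and 10.64 on the conventional arrays and 8.81 and 8.73 on the germ-free arrays, beside the enterocyte values above.

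**Figure D2:**
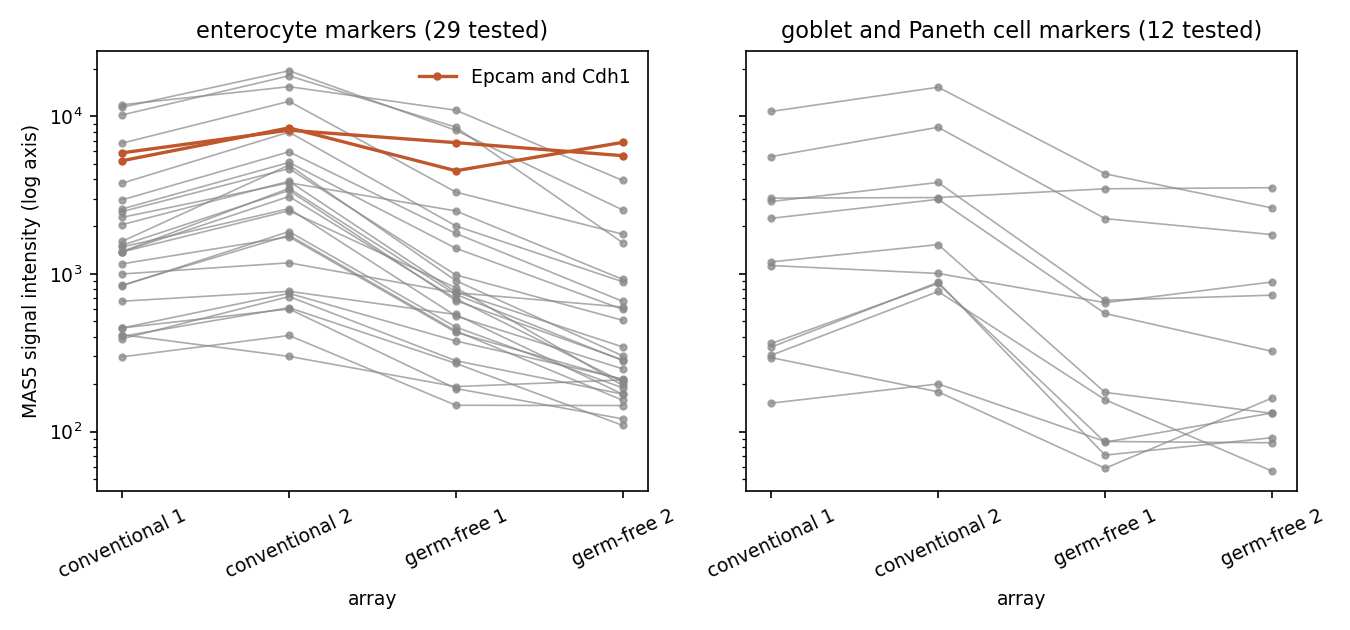
MAS5 signal intensity (log axis) of the 29 tested enterocyte markers and the 12 tested goblet and Paneth cell markers on each of the 4 arrays. Each line joins the values of 1 gene across arrays and stands for no time course; 28 of the 29 enterocyte markers lie higher on conventional 2 than on conventional 1, and 27 lie higher on germ-free 1 than on germ-free 2.

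Antimicrobial and mucosal defence proteins had higher values for all 12 tested members, with a median log2 difference of 1.42 (2.67-fold). After Reg3b and Reg3g, the members with the smallest p were Reg1, a secreted lectin of the same family (3.56-fold), and Lyz1, the lysozyme of Paneth cells (5.06-fold), neither past the threshold over all genes. The log2 difference of Lyz1 was 2.34, with 1.7 without conventional replicate 2 and 2.98 without conventional replicate 1. Its germ-free signals, 70.9 and 91.4, lay under the filter's signal. A second probe set of Reg3b had a log2 difference of 2.73. In this list 1 member passed over all genes tested and 8 adjusted over the list alone. Camera gave an adjusted p of 5.38e-11, and the adjusted p was 0.591 with an estimated correlation. Lyz1 and Itln1 belong to the goblet and Paneth list as well, and Lyz2 to the myeloid list. The epithelial markers were higher on the same arrays. Probe sets of the Reg3 family and of the lysozymes target similar sequences, so that signal shared between paralogs was not separated.

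Genes that define and arm gamma-delta T cells differed less than those of epithelium. Cd3e, a chain of the receptor complex, was at 9285 ± 236 in conventional and 8809 ± 1.15 in germ-free arrays (SD, n = 2 each; log2 0.08, SE 0.11). The cytotoxic granule proteases Gzma and Gzmb had log2 differences of -0.33 (SE 0.16) and -0.23 (SE 0.11), the pore-forming Prf1 of 0.16 (SE 0.24), and Itgae, the integrin chain that binds epithelial E-cadherin, of -0.22 (SE 0.11). None of these passed by limma (adjusted p 0.576 to 0.854). Without 1 array the log2 difference ran from -0.18 to 0.49 for Prf1 and from -0.54 to -0.12 for Gzma. It ran from -0.33 to -0.139 for Gzmb and from -0.299 to -0.145 for Itgae. The signals of Gzma and Gzmb reached 37068 and 31271 on germ-free 1, where the highest signal of any probe set was 38594. Whether differences are compressed so near the top of the range was not tested. The cytokine gene Ifng lay below the filter, at 115 ± 78.0 and 110 ± 3.40 (SD, n = 2 each), and was not tested. The receptor and CD3 list had lower values for 11 of 14 members (median log2 -0.16, camera adjusted p = 0.0488, adjusted p = 0.766 with an estimated correlation), with 0 members called. The epithelial markers were higher on the conventional arrays, where these values were lower. The list's members with the smallest p were Themis, a regulator of T cell receptor signalling (log2 -0.62), and the receptor variable segments Trgv4 and Trgv1. The log2 difference was -0.34 for Trgv4 (-0.18 without germ-free replicate 1) and -0.26 for Trgv1. Within the groups Trgv4 was higher on conventional 2 and on germ-free 1, where the enterocyte markers were also higher. Themis was so only in the conventional and Trgv1 only in the germ-free arrays. Other probe sets of Themis had log2 differences of -0.34, -0.03 and 0.09, and other probe sets of Trgv4 of -0.35 and 0.04. The list's call held under 5 of 16 alternatives (adjusted p 0.042 to 0.988); it ended without conventional replicate 1 (0.0774), conventional replicate 2 (0.201) or germ-free replicate 1 (0.25), and with quantile normalization its mean was -0.01.

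Natural killer receptors and their adaptors, which IEL share with natural killer cells, had lower values in the conventional arrays for 12 of 15 tested members, with a median log2 difference of -0.29. The members with the smallest p were the adhesion receptors Crtam (log2 -0.59, SE 0.14) and Cd96 (log2 -0.39, SE 0.12) and the signalling adaptors Tyrobp (log2 -0.32, SE 0.10) and Fcer1g (log2 -0.32, SE 0.11). In this list 0 members passed over all genes tested and 0 adjusted over the list alone. Camera gave an adjusted p of 0.00889, and the adjusted p was 0.663 with an estimated correlation. The call held under 10 of 16 alternatives (camera adjusted p 0.00159 to 0.663). It ended with quantile normalization (0.0952), without a filter (0.147) and with the enterocyte covariate (0.202). It also ended without conventional replicate 2 (mean log2 -0.156) and without germ-free replicate 1 (-0.188). The epithelial markers were higher on the conventional arrays, where these values were lower. Within the groups Tyrobp and Fcer1g were higher on conventional 2 and on germ-free 1, where the enterocyte markers were also higher. Crtam was so only in the conventional and Cd96 only in the germ-free arrays.

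Other lymphocyte lists did not pass. The median log2 differences were -0.18 for cytotoxic granule proteins and death receptor ligands (camera adjusted p = 0.379), -0.11 for homing and adhesion receptors (0.147), -0.04 for cytokine receptors (0.693), 0.03 for transcription factors (0.764), 0.04 for cytokines and growth factors (0.831) and 0.10 for chemokines (0.626). Among the chemokines 2 members passed adjusted over the list alone: Ccl25, which epithelium makes and which attracts gut-homing T cells, with a higher value (3.42-fold), and Xcl1, which T cells and natural killer cells secrete, with a lower one (log2 -0.68; -0.39 without conventional replicate 1 and -0.98 without conventional replicate 2). In the 5 other lists 0 members passed adjusted over the list alone. Ccr2, a chemokine receptor of the homing list, had a signal of 68.4 ± 55.8 in conventional and 247 ± 13.6 in germ-free arrays (SD, n = 2 each; log2 -1.54, SE 0.40, limma adjusted p = 0.242). Its conventional signals, 108 and 29.0, lay under the filter's signal, and the difference was -0.97 without conventional replicate 2.

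Cell cycle and mitosis genes had higher values in the conventional arrays for 26 of 30 tested members, with a median log2 difference of 0.37. Cdc20, Ube2c, Kif11 and Plk1, which act in mitosis, had the smallest p, with values 1.47-fold to 1.64-fold higher. Probe sets of Kif11 ran from a log2 difference of 0.19 to 0.71. In this list 0 members passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 7.68e-05, and the adjusted p was 0.808 with an estimated correlation. The list's mean log2 value was 10.05 and 10.19 on the conventional arrays, 9.99 on germ-free 1 and 9.58 on germ-free 2. Without germ-free replicate 2 the mean difference was 0.13 (adjusted p = 0.263), and those of Ube2c and Kif11 were 0.40 (0.69 and 0.71 with it). The enterocyte markers were lowest on the same array, and with their mean as a covariate, an alternative chosen after seeing the data, the difference was -0.19 (adjusted p = 0.0728; 2.15e-10 to 0.808 over 16 alternatives).

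Type I interferon-stimulated genes had higher values for 17 of 23 tested members (median log2 0.21, camera adjusted p = 0.0254, adjusted p = 0.663 with an estimated correlation). The examples with the smallest p were Oasl1 (log2 0.94, SE 0.26), Irf7, the transcription factor that amplifies the interferon response (log2 0.66, SE 0.20), Cmpk2 (log2 1.31, SE 0.41; 0.86 without conventional replicate 2) and Ifit1 (log2 0.90, SE 0.28). Of the list's members 0 passed over all genes or adjusted over the list alone. The call held under 11 of 16 alternatives (adjusted p 0.00586 to 0.663); it ended without conventional replicate 2 (0.22), without germ-free replicate 1 (0.0818) and without germ-free replicate 2 (0.0632), and the epithelial markers were higher on the same arrays. Genes induced by interferon-gamma (median log2 -0.06, camera adjusted p = 0.52) and Toll-like receptor and NF-kappaB signalling genes (-0.03, 0.835) did not pass; the mean of the latter was 0.01 although its median and its test pointed down, and in both lists 0 members passed adjusted over the list alone. Myd88, the adaptor of most Toll-like receptors, had a log2 difference of -0.13 (SE 0.17; -0.32 to 0.06 without 1 array).

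Immediate-early activation genes had a median log2 difference of -0.14 but a mean of 0.01, and camera placed them lower without passing (adjusted p = 0.46). Among them 1 member, Klf4, a transcription factor found in differentiated gut epithelium, passed adjusted over the list alone (3.66-fold higher, limma adjusted p = 0.109 over all genes). Dusp1, a phosphatase that restrains stress kinases, had a lower value (log2 -0.97, SE 0.31, limma adjusted p = 0.384), with signals of 1928 and 965 on germ-free 1 and 2 and a log2 difference of -0.48 without germ-free replicate 1 and -1.46 without germ-free replicate 2. Antioxidant genes had a median of 0.11 (camera adjusted p = 0.354), with 2 of 20 members called adjusted over the list alone; the metallothionein Mt1 was 2.73-fold and the glutathione transferase Gsta4 3.99-fold higher in value. Both ran in the order of the enterocyte markers across the arrays, from conventional 2 through conventional 1 and germ-free 1 to germ-free 2; the log2 difference of Gsta4 was 2.00, and 1.26 without conventional replicate 2, and that of Mt1 was 1.45, and 0.94 without germ-free replicate 2. Heat shock genes (median log2 -0.06, camera adjusted p = 0.445) and genes of the unfolded protein response (-0.08, 0.52) did not pass, with 0 members called adjusted over the list alone. The heat shock list was called lower without conventional replicate 2 (mean log2 -0.19, adjusted p = 0.00682) and with the enterocyte covariate (-0.46, 9.08e-05), while without conventional replicate 1 its mean was 0.14; over 16 alternatives the adjusted p ran up to 0.993.

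Among metabolic lists, cytosolic ribosomal protein genes had lower values in the conventional arrays for 26 of 26 tested members, with a median log2 difference of -0.23. They were shifted down by camera (adjusted p = 1.75e-06), but the adjusted p was 0.766 with an estimated correlation, and the mean was -0.06 with quantile normalization (adjusted p = 0.732; 9.98e-07 to 0.766 over 16 alternatives). The epithelial markers were higher on the conventional arrays, where the ribosomal values were lower. Within the groups Rpl19, Rpl8 and Rpl35 were higher on conventional 2 and on germ-free 1, where the enterocyte markers were also higher. Rps15 was so only in the conventional arrays. With the enterocyte covariate, from 1 residual degree of freedom, the ribosomal list kept its call. Cholesterol synthesis genes had lower values for 15 of 20 members (median log2 -0.21, camera adjusted p = 0.0144, adjusted p = 0.808 with an estimated correlation). Ebp and Nsdhl, enzymes of that pathway, had log2 differences of -0.41 (SE 0.13) and -0.33 (SE 0.15). Without conventional replicate 2 the mean of the cholesterol list was 0.01 (adjusted p = 0.817), without germ-free replicate 2 it was -0.11 (0.288), with quantile normalization -0.17 (0.0952), and with the enterocyte covariate 0.28 (0.172); over 16 alternatives the adjusted p ran from 1.5e-05 to 0.817. Oxidative phosphorylation (median log2 -0.09, camera adjusted p = 0.0805), glycolysis (0.01, 0.876) and circadian clock genes (0.04, 0.831) did not pass. The oxidative phosphorylation list was called lower with the mean of all probe sets (adjusted p = 0.0281) and without germ-free replicate 2 (0.0184); over 16 alternatives the adjusted p ran up to 0.857. In all 5 metabolic and clock lists 0 members passed over all genes or adjusted over the list alone. The means of the cytotoxic, interferon-gamma, Toll-like receptor, immediate-early, heat shock, glycolysis, oxidative phosphorylation, circadian and stromal lists, none of which passed, changed sign with median centring or quantile normalization.

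**Figure D3:**
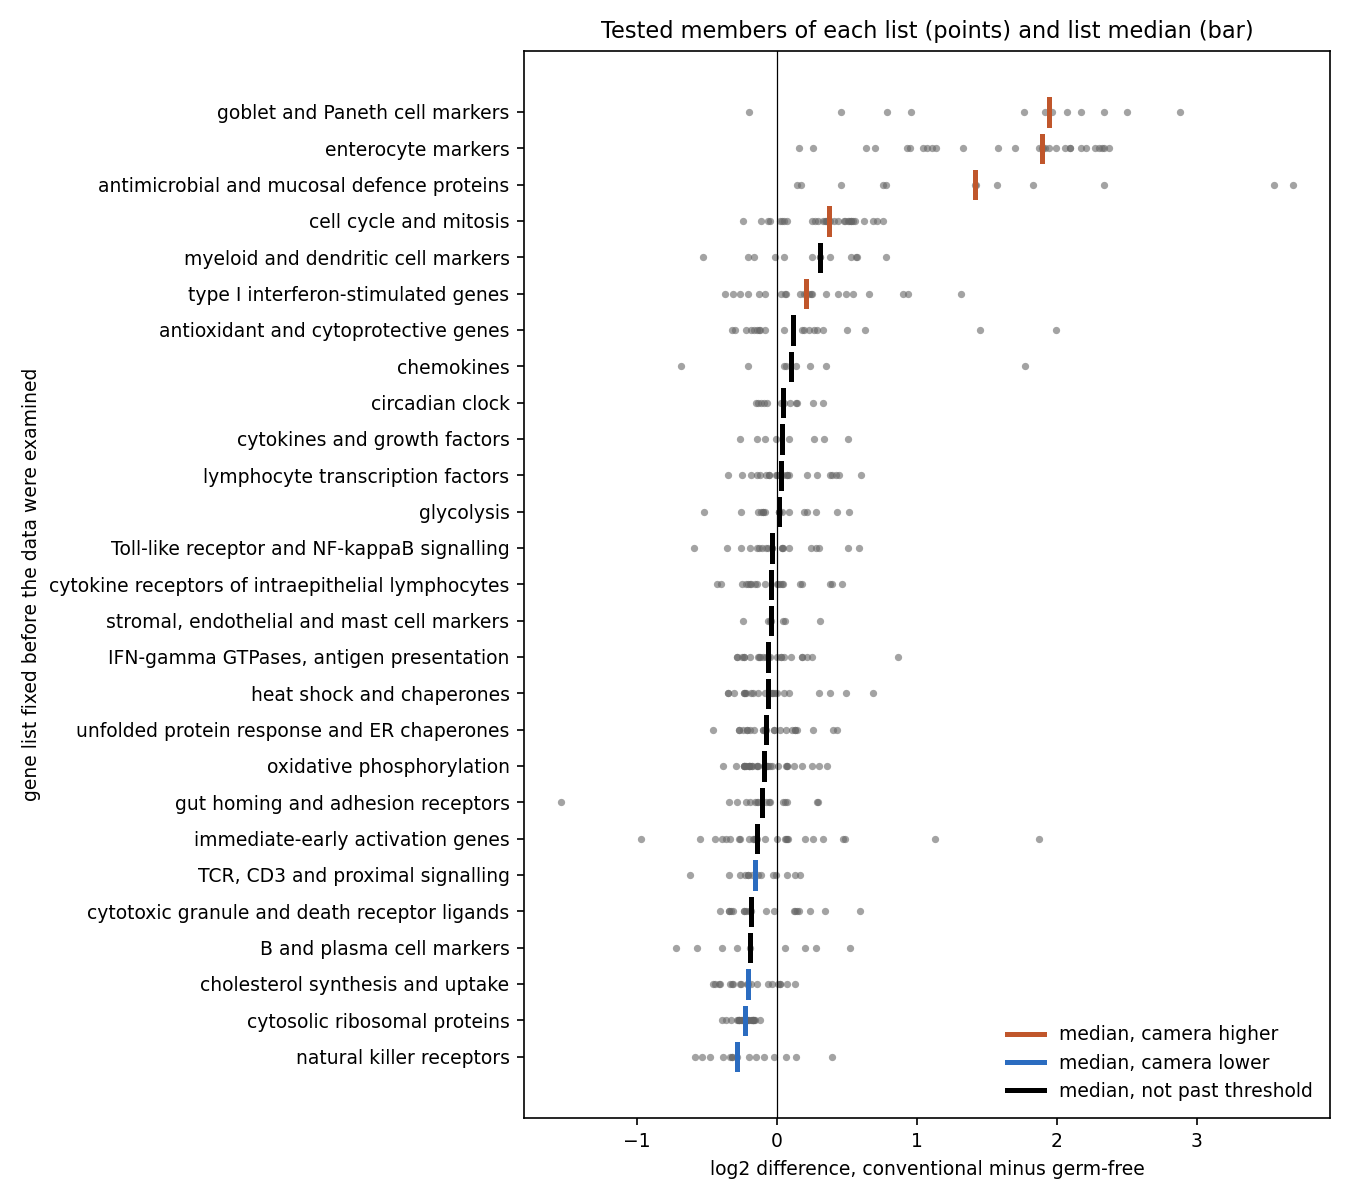
Log2 difference, conventional minus germ-free, of each tested member (points) of the 27 lists with at least 5 tested members, with the list median as a bar coloured by the camera call with its preset correlation. The goblet, enterocyte and antimicrobial lists stand apart, with medians of 1.94, 1.89 and 1.42, and 0 of the 9 called lists keep their call with an estimated correlation. That last test rests on 2 residual degrees of freedom and could hardly call any list.

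Markers of other cell types that a sort could hold differed less than those of epithelium. Myeloid and dendritic cell markers had a median log2 difference of 0.31 (camera adjusted p = 0.246), and B and plasma cell markers of -0.19 (0.479). The myeloid list's mean was 0.02 without conventional replicate 1, and 0.42 without conventional replicate 2, where the list was called higher (adjusted p = 0.0231; up to 0.955 over 16 alternatives). Ighm, the immunoglobulin mu chain, was the only marker of these called adjusted over the list alone (log2 -0.72, SE 0.18, limma adjusted p = 0.225; -0.47 without conventional replicate 1), and its probe sets differed in sign. Stromal, endothelial and mast cell markers had a median below 0 (-0.04), a mean just above it and a test that pointed down (camera adjusted p = 0.835). The alpha-beta T cell markers and the targets of the aryl hydrocarbon receptor, which senses dietary and microbial ligands, had fewer than 5 tested members and no list test; Thy1 had a log2 difference of -0.52 (SE 0.15, limma adjusted p = 0.318, or 0.0446 adjusted over the list alone) and Cyp1a1 of 0.97 (SE 0.36, limma adjusted p = 0.478; 0.43 without conventional replicate 2 and 1.5 without conventional replicate 1).

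By size alone, 105 genes were at least 2-fold higher in conventional arrays in all 4 array pairs and 0 were at least 2-fold lower. Splitting the 4 arrays in the other 2 ways gave 3 and 7 such genes. The 2 epithelial lists supplied 14 of the 105 genes, from 41 members tested (Fisher's exact test, odds ratio 61.8, p = 5.93e-19, over genes, which are not independent). Of the 105 genes, 87 (82.9%) were also higher on conventional 2 than on conventional 1 and on germ-free 1 than on germ-free 2, the order of the enterocyte markers, against 22.6% of all tested genes. Leaving out an array raised the count, since fewer pairs then had to be 2-fold apart. It ran from 154 without conventional replicate 2 to 347 without conventional replicate 1, and the cause of that range was not tested. The groups did not overlap for 42.4% of the tested genes, against 33.3% by chance. None of the lower genes with the smallest p passed the threshold (limma adjusted p from 0.117 to 0.184). They were Chrac1, a chromatin accessibility factor (log2 -0.97, SE 0.15), and Rgs2, a brake on G protein signalling (log2 -0.79, SE 0.13). Next came the RNA host gene Snhg12 (log2 -0.91, SE 0.18), Mmgt2 (log2 -0.85, SE 0.17), Epm2aip1 (log2 -0.77, SE 0.16) and Elavl4 (log2 -0.87, SE 0.19). Over the probe sets above the filter, the log2 difference ran from -0.97 to -0.35 for Chrac1 and from -0.77 to -0.10 for Epm2aip1. It ran from -1.07 to -0.73 for Rgs2 and from -0.87 to -0.80 for Elavl4.

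The sample checks separated germ-free 1 from the other arrays. The groups were sex-matched per the series' design text, and Y-linked genes and Xist, which males and females respectively express, are markers of the sex mix of a pool. The Y-linked Eif2s3y had a signal of 1214 there and of 2546 to 3269 elsewhere, and Xist, expressed from the inactive X chromosome, had 13337 there and 8797 to 9284 elsewhere. Other probe sets of Xist differed in sign between the groups (log2 -0.96 and 0.86), but each read highest on germ-free 1 (3097 and 2022). The Y-linked Uty (428 there, 928 to 1090 elsewhere) and Kdm5d (399 there, 569 to 731 elsewhere) were lowest on that array. The control probe set for the 5′ part of 18S ribosomal RNA read 4685 on germ-free 1 and 1054 to 1758 on the others. The 3′ to 5′ signal ratios of the beta-actin controls, a gauge of RNA integrity after amplification, were 1.33 and 1.26 on the conventional and 1.36 and 1.38 on the germ-free arrays, and those of Gapdh 0.838 and 0.803 on the conventional and 1.01 and 0.875 on the germ-free arrays. The spiked hybridisation controls were higher on replicate 2 of both groups; CreX read 14600 and 22140 on the conventional and 18250 and 23750 on the germ-free arrays.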

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

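The fit with the enterocyte covariate was chosen after seeing the data; the other alternatives were planned. Of 1990 values of named genes under alternatives, 1938 kept their side of the threshold, 29 lost a call, 23 gained one and 0 called directions reversed; where neither value passed, the sign changed in 36 gene and 39 list values. Fits that leave out an array keep 1 array in a group, which is assumed to vary like the other group. The log2 range was 2.9 to 4.2 for Reg3b (called in 10 of 15 alternatives, adjusted p 0.00842 to 0.143), 1.57 to 3.15 for Clca1 (8 of 15, 0.00862 to 0.212), 1.97 to 2.37 for Fcgbp (8 of 15, 0.00862 to 0.212) and 1.61 to 2.14 for Slc6a20a (5 of 15, 0.0218 to 0.356). Dim signal near background limits the lower end, as for Reg3g in germ-free arrays.

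The 4 genes higher became 0 with no filter, with the mean of all probe sets and with no intensity trend, 7 with the stricter filter, 8 with the added constant doubled, 12 probe sets when every probe set was tested, 17 at an adjusted p under 0.10 and 8 with the enterocyte covariate, which shared 2 genes and called 12 lower against 0. Without each array in turn the range was 0 to 111 higher and 0 to 1 lower. Genes at least 2-fold apart numbered 54 with the stricter filter, where fewer genes were tested, and 154 to 347 without each array in turn. The replicate numbers are shared by the groups, but the genes of same-numbered arrays did not deviate together (correlation -0.0931), although the spiked hybridisation controls were higher on replicate 2 of both groups (BioDn 2010 and 3325, 2305 and 3789). The fit with the replicate block called 0 genes higher (Reg3b and Fcgbp adjusted p = 0.0604, Clca1 0.105, Slc6a20a 0.226), with 663 higher at an unadjusted p under 0.05, and 8 lists, with the T cell receptor list at -0.14 (adjusted p = 0.0767).

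The 9 lists past the threshold became 5 with quantile normalization and 4 with the enterocyte covariate. They became 0 with an estimated inter-gene correlation, a test on 2 residual degrees of freedom that could hardly call any list. That last setting leaves each mean as it was (1.6 enterocyte, 1.64 goblet, 1.51 antimicrobial, 0.34 cell cycle, 0.25 interferon, -0.23 ribosomal, -0.21 natural killer, -0.19 cholesterol, -0.14 T cell receptor). With quantile normalization the means without a call were -0.056 (ribosomal), -0.18 (natural killer), -0.17 (cholesterol) and -0.0149 (T cell receptor, where camera's direction turned upward). With the enterocyte covariate, from 1 residual degree of freedom, the cell cycle (-0.19) and cholesterol (0.28) lists reversed in sign without a call. The T cell receptor (-0.17), natural killer (-0.17) and interferon lists (0.15) lost their calls with it. The enterocyte list itself has no value there, since the covariate is its own mean. The T cell receptor list also lost its call with no added constant (-0.14), the mean of all probe sets (-0.10), no filter (-0.0705) and the stricter filter (-0.14), and the natural killer list with no filter (-0.10). Without each array in turn the means ranged from 0.13 to 0.54 (cell cycle), -0.39 to 0.00754 (cholesterol), -0.18 to -0.10 (T cell receptor), -0.26 to -0.16 (natural killer) and 0.17 to 0.32 (interferon). Among lists that did not pass, heat shock, oxidative phosphorylation and myeloid gained a call under 2, 2 and 1 of 16 alternatives. Apart from the cases where fewer genes or arrays entered, the cause was not tested.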

Other observations

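The tests of the epithelial markers, of Reg3b, Reg3g and Clca1, of Epcam and Cdh1, of the 10 further Snhg genes, the nearest-abundance and widened ranges, the medians without 1 member and the bound for 2 degrees of freedom were chosen after the results were seen; the matched-list tests of the T cell receptor, natural killer, ribosomal and full Snhg lists were written before.

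A family outside the lists was lower in value in the conventional arrays: the host genes of small nucleolar RNAs, whose transcripts carry guides for ribosomal RNA modification. Of 14 tested genes named Snhg or Gas5, 12 had lower values, 6 of them at an unadjusted limma p under 0.05 and 0 past the adjusted threshold. Their median log2 difference was -0.39, set against -0.15 to 0.16 for the central 95% of 10000 expression-matched random lists (camera p = 4.04e-05, p = 0.0692 with an estimated correlation). The family was taken up because Snhg1, Snhg8, Snhg12 and Gas5 stood out, so its own median excludes nothing. The 10 others had a median of -0.22 with 8 lower values, just below the widened range for lists of the nearest genes in abundance (-0.20 to 0.31), and without 1 member that median ran from -0.28 to -0.16, inside the range in 5 of 10 cases. Scaling or dilution that shifts transcripts of one abundance alike therefore cannot be told apart from a lower expression of these genes in colonised mice.

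When each probe set was tested alone, 12 probe sets passed, among them those of 6 genes that were not called per gene: Muc2, Cyp3a25 and Reg3g (adjusted p = 0.0318, 0.0318 and 0.0336) and 3 others. Zg16, a goblet cell lectin of the goblet and Paneth list, passed with 2 probe sets (log2 2.37 and 2.52), Pigr, the epithelial receptor that carries immunoglobulin A, with 2 (log2 2.92 and 2.68), and Papss2, an enzyme that makes the donor for sulfation, with 1 (log2 2.33). These 3 genes were chosen after their values were seen.

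The higher enterocyte and goblet transcripts have a candidate explanation in epithelial cells or RNA that stayed in the sort in differing amounts: 28 of 29 enterocyte markers were also higher on conventional 2 than on conventional 1 (median log2 0.82) and 27 of 29 higher on germ-free 1 than on germ-free 2 (1.14), outside the central 95% of matched random lists both times. The median difference of all tested genes, -0.000205, is largely set by the scaling of every array to the same trimmed mean, so it is no test of the scaling factor. Since 1 factor per array moves all genes alike, it does not by itself set the enterocyte markers (1.89) apart from the other genes. Whether that epithelium held enterocytes and goblet cells in one proportion cannot be told apart: the goblet list did not move between the germ-free arrays (median -0.00156), which was first read as excluding a fixed proportion, but it sets 1 array against 1, and the germ-free mean of 5 of the 12 members lay under the filter's signal (2 members did on both arrays); the 7 others had a median of 0.33, with 4 higher on germ-free 1. Epcam and Cdh1 had log2 differences of 0.16 (SE 0.19) and 0.26 (SE 0.27). They lay 9.40 and 6.15 standard errors below the median of the 27 other markers (1.90), at signals of 4513 and more. These are each gene's own standard errors and take that median as fixed. The enterocyte mean itself differed within the groups (10.74 and 11.49 on the conventional, 10.03 and 9.01 on the germ-free arrays). The distances therefore cannot decide whether carried-over epithelium was the main source of their signal, and the sorted lymphocytes are an untested one. A difference between the epithelia of colonised and germ-free mice, and expression of the markers by the lymphocytes, stay open and untested.

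Reg3b, Reg3g and Clca1 differed by more than any enterocyte marker, the highest of which was Lct (log2 2.37). Relative to the enterocyte mean of each array their excess was 2.09 (SE 0.52), 1.95 (SE 1.02) and 1.28 (SE 0.39), and 1.77 (SE 0.62) on average. Carry-over alone, from an epithelium of the same expression and make-up in both groups, was first read as excluded, but it cannot be told apart: the 3 genes were picked for their size, Reg3g lay near background on the germ-free arrays, and the mean excess of 2.88 standard errors is under the 4.30 that 2 degrees of freedom need. Also open, as untested hypotheses, are a rise of these transcripts with colonisation in the carried-over epithelium or in the lymphocytes, and a changed share of secretory cells. With the enterocyte covariate the log2 differences were 2.90 for Reg3b, 3.99 for Reg3g and 2.25 for Clca1, all called by limma from 1 residual degree of freedom.

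The lymphocyte and ribosomal lists with lower values have a candidate technical explanation in scaling or dilution that lowers abundant transcripts alike, and the T cell receptor list (median log2 -0.156) lay within the range of matched random lists (-0.22 to -0.04), as that explanation needs. The natural killer list (-0.286) lay outside its range (-0.20 to 0.06), also against its nearest genes in abundance and without any 1 member (-0.30 to -0.24). This range comes from unrelated genes and was not widened, since the list's estimated correlation was -0.0542. That estimate rests on 2 residual degrees of freedom, so a shift by abundance as the whole cause cannot be excluded there. Also open and untested are a lower expression in colonised mice and dilution by epithelial RNA of transcripts that only lymphocytes make. The epithelial markers were higher on the conventional arrays, where these values were lower. Within the groups, though, Tyrobp and Fcer1g were higher where the enterocyte markers were higher, and Crtam and Cd96 were so in 1 group each. With their covariate the natural killer mean was -0.17, against -0.21 without it, in a fit with 1 residual degree of freedom. The call ended there (camera adjusted p = 0.202, and 0.00159 to 0.663 over 16 alternatives), which does not show that epithelial content accounts for the lower values. The ribosomal list (-0.225) lay below the bound of -0.21 set before its result was seen, and also below that of its nearest genes in abundance (-0.22); after this was seen, the range was widened for the list's estimated correlation of 0.297, since random lists hold unrelated genes, and the widened range (-0.28 to -0.07) holds it. It therefore cannot be told apart, with 22 of the 26 members among the 100 most abundant genes, where few others can be matched, and a mean of -0.06 after quantile normalization.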
